A study of Mus musculus with 12 samples.

How the data were processed

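Skeletal muscle RNA of 6 wild-type (WT) and 6 Nur77-overexpressing transgenic (TG) mice, fasted overnight, was pooled by 2 mice into 3 WT and 3 TG pools, per the labels. Each pool was labelled with Cy3 and hybridised to 1 single-colour Illumina array on each of 2 chips, which gave 12 arrays with 45281 probes each. The scanner software and any processing tool were not given in the sources used here.

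The deposited signals are probe intensity values on a linear scale, headed as non-normalized per the file headers. They had nevertheless been background-subtracted and scaled before deposit: between 29.3% and 32.8% of the values per array were below 0 and the mean signal was 472.135 on all 12 arrays. The deposited detection score per probe is headed as a p-value per the file headers, but it rose with the signal (Spearman of at least 0.975 on each array) and was therefore read as 1 minus the detection p. The authors' deposited value table holds log2 values, and was rebuilt from the signals to within 0.00109 as log2 of the signal floored at 1, minus the 75th percentile of each array, minus the median of each probe over the 12 arrays. Its direction is that of the signal, and its column medians lay between -0.251 and 0.0935.

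The design fixed before the data were examined named background correction from control probes or detection values (neqc) as the main setting and normexp with an offset of 50 as the fallback where signals were already background-subtracted. The fallback therefore applied, followed by quantile normalisation and log2 in limma. Normexp on values that were already background-subtracted compresses differences of dim probes. The 2 arrays of a pool were averaged, and probes with a detection p below 0.05 on all 6 arrays of at least 1 genotype were kept (15708). The number detected per array, 17607 to 19118, gives the signal over background. The precision is set by 3 pools per genotype, and an exact permutation test of 3 against 3 pools cannot go below 0.1.

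Probes were named through the platform annotation, which can be old. It listed 34903 probes, 34885 with 1 gene symbol and 18 with several genes, which were not named, and 10378 probes were without a gene here. Updating symbols through Entrez numbers changed 0. A gene was represented by its kept probe with the highest mean, which gave 9131 genes. No gene named by the rule below had probes called in opposite directions, and genes chosen after their values were seen were not checked for this. Some named genes had further probes that were not called. Log2 differences ranged from -0.11 to 0.78 for Dlst (2 of 4 probes called), 0.24 to 0.55 for Crat (1 of 3) and -0.08 to 0.35 for Pecam1 (1 of 3). They ranged from -0.78 to -0.28 for Per1 (2 of 3) and from -0.36 to -0.24 for Ccn1 (2 of 3). For Pkm, Psmb8, Med1 and Smtn 1 of 2 probes was called. For a gene undetected on all arrays of 1 genotype, the fold is a lower bound, taken against the lowest detected signal of each array or the probe's own value, whichever was higher.

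Genotypes were compared with limma 3.58.1 (lmFit and eBayes, two-sided) in R 4.3.3 on the 6 pool means, with Benjamini-Hochberg adjustment over all kept probes and a threshold of 0.05. The chip effect and its dependence on genotype were tested with limma on the 6 differences between chips. The 33 gene lists covered energy metabolism, contractile genes, growth, atrophy, other cell types and handling effects. The 30 lists with at least 3 tested genes were tested with camera (preset correlation 0.01, adjusted over the lists), with fry and with camera at an estimated correlation beside it. The NR4A receptors (0 tested genes), blood (2) and sex-linked (2) lists were too small. Counts adjusted over the list alone used the p-values of that list's genes.

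Genes were named by a rule fixed before the data were examined: Nr4a1, Nr4a2 and Nr4a3; the 12 largest rises and 12 largest falls among called genes whose 3 TG pools lay on 1 side of the 3 WT pools; up to 4 members per list with the smallest p; and genes with probes called in opposite directions (0). Other genes are said to have been chosen after their values were seen.

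The fit was tested on simulated data for the comparison of 3 against 3 pools with 15708 probes, of which 200 were changed. It recovered 92.4% of the 1.5-fold, 100% of the 2-fold and 100% of the 4-fold changes with 14 false calls, and made 0 calls with no change. The list test recovered a median of 0.47 for a simulated shift of 0.5 in the TCA cycle list. The simulated noise was independent between probes. It therefore does not show how either test behaves where genes are correlated or whole lists shift between pools.

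The alternatives were no background correction (signals floored at 10), scaling to the 75th percentile, cyclic loess, the authors' table, no filter, a detection p below 0.01 on all arrays, each chip alone, 12 arrays with the chip as a block with and without the pool as a random block (statmod 1.5.0), the pool number as a block, trended and robust variance, each pool left out, other thresholds, 1 probe per gene and averaged probes. Chosen after seeing the data were neqc from the detection scores (offset 16), WT1 from chip 1 only, and WT1 from chip 1 only without TG3.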

Results

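Gene expression was measured in skeletal muscle of wild-type (WT) mice and of transgenic (TG) mice overexpressing Nur77, the orphan nuclear receptor encoded by Nr4a1, all fasted overnight. RNA of 12 mice, 6 per genotype, was combined in pools of 2 mice, which gave 3 WT and 3 TG pools. Per the labels, each pool was hybridised to 1 Illumina mouse whole-genome BeadChip array on each of 2 chips. The pool was therefore taken as the replicate (n = 3 per genotype) and the 12 arrays as technical repeats of 6 pools. Between 17607 and 19118 of the 45281 probes were detected per array, and 15708 probes detected on all 6 arrays of at least 1 genotype were tested. The number of pools limits the precision.

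The first principal component held 57.8% of the variance and separated the genotypes, with the 6 WT arrays between -30.0 and -12.7 and the 6 TG arrays between 15.7 and 40.7. The second component (15.5%) set the chip 2 array of pool WT1 (-28.3) and both arrays of pool TG3 (-12.3 and -17.9) apart from the others, which lay between -1.06 and 15.7. Arrays of different genotypes differed by a median root mean square of 0.43 log2 units. The median was 0.23 for the 6 pairs of arrays of 1 pool, which lay on different chips. It was 0.27 for arrays of different pools of 1 genotype on 1 chip and 0.28 for those on different chips. The nearest array was the other array of the same pool for 2 of the 12 arrays, and an array of the same chip for the rest.

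**Figure D1:**
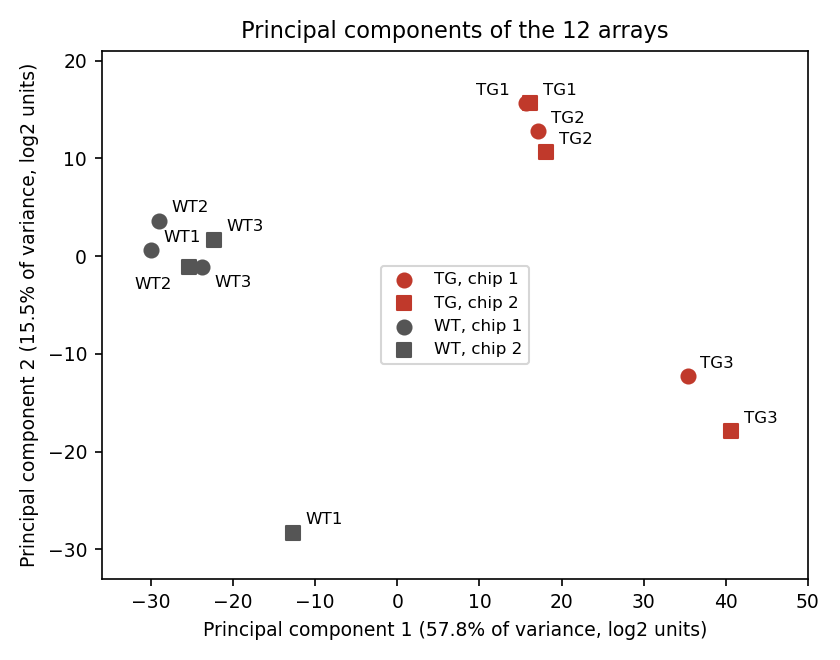
Scores of the 12 arrays on the first (x axis, 57.8% of the variance) and second (y axis, 15.5%) principal components of normalised log2 intensity over 15708 probes, by genotype and chip. The WT arrays lie at -12.7 or lower on the first component and the TG arrays at 15.7 or higher.

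The genotype comparison asked which transcripts differ in muscle that overexpresses Nur77. Nr4a1 itself gave no check of the labels, because its probe on the array (ILMN_2701881) was detected on 0 of 12 arrays, with signals between -16.2 and 8.2. Its log2 difference was -0.02 ± 0.06 (SE, n = 3 pools per genotype), with an exact two-sided permutation p of 0.7, where 0.1 was the smallest possible, and its sign changed between processing settings. Whether this probe lies within the transgene was not known here. Of the related receptors, Nr4a2 was detected on 7 arrays (log2 difference 0.03 ± 0.08, SE), and the 3 probes of Nr4a3 were detected on 0, 0 and 4 arrays.

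With the background correction used here, the largest rise in TG muscle was that of Myh8, the perinatal myosin heavy chain, which was 55.5-fold higher (log2 5.79 ± 0.50, SE, adjusted p = 0.000252 by limma, n = 3 pools per genotype). It was 5.12 without TG3 and 6.27 without TG1. Igf2, a fetal growth factor, rose by 2.70 ± 0.14 on the log2 scale from an already high WT level of 11.1. The largest fall with this correction was that of Odf3l2, a relative of a sperm-tail outer dense fibre gene, which was 45.3-fold lower (log2 -5.50 ± 0.27, SE). Rasd2, a Ras-related small GTPase (log2 -3.69 ± 0.10), Amd2, an S-adenosylmethionine decarboxylase of polyamine synthesis (-2.87 ± 0.16), and Gdap1, a protein of the mitochondrial outer membrane (-2.85 ± 0.09), also fell. These and the other genes with the 12 largest rises and the 12 largest falls were chosen among genes whose 3 TG pools lay on 1 side of the 3 WT pools.

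The other large rises, as log2 differences, were those of Mrvi1 (4.44), a substrate of cGMP-dependent protein kinase, Aldh1a7 (4.17, 3.94 to 8.41 among alternatives), an aldehyde dehydrogenase detected on only 1 of 6 WT arrays, so that the background sets its size, Igfn1 (3.82), an immunoglobulin-like and fibronectin-domain protein of skeletal muscle, and Rom1 (3.48), a membrane protein of photoreceptor outer segments. Tinag (3.37, 3.17 to 5.38 among alternatives, detected on 3 of 6 WT arrays), Slc45a3 (3.18), the organic cation transporter Slc22a4 (2.92), the actin-binding protein Cotl1 (2.81) and the cytoskeletal protein Epb41l1 (2.65) followed. Cd200r3, a CD200 receptor relative, was detected on 0 of 6 WT arrays and was at least 5.19-fold higher in TG, taken against the lowest detected signal of each WT array. Cotl1 in WT rested on unequal arrays, with 10.3 on the chip 2 array of WT1. The other large falls were those of the transcription factor Tfcp2l1 (-2.82), the zinc transporter Slc30a2 (-2.79), the pseudogene Hmga2-ps1 (-2.56), the cadherin Cdh4 (-2.53), Tmem100 (-2.43), Lrrc30 (-2.39), the mitochondrial protein Mss51 (-2.29) and Ppp1r1a (-2.29), an inhibitor of protein phosphatase 1. Odf3l2 and Cdh4 were each detected on 4 of 6 TG arrays and ranged from -7.53 to -4.97 and from -4.67 to -2.36 among alternatives. The size of these changes depended on the background correction, as did that of Slc22a4 (4.55 without it), Gdap1 (-4.52) and Slc30a2 (-4.25). The same held for Slc45a3 (4.67 without it), Igfn1 (4.94), Epb41l1 (3.57) and Hmga2-ps1 (-3.68). Amd2 and Hmga2-ps1 have close sequence relatives whose transcripts the probes were not checked against.

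**Figure D2:**
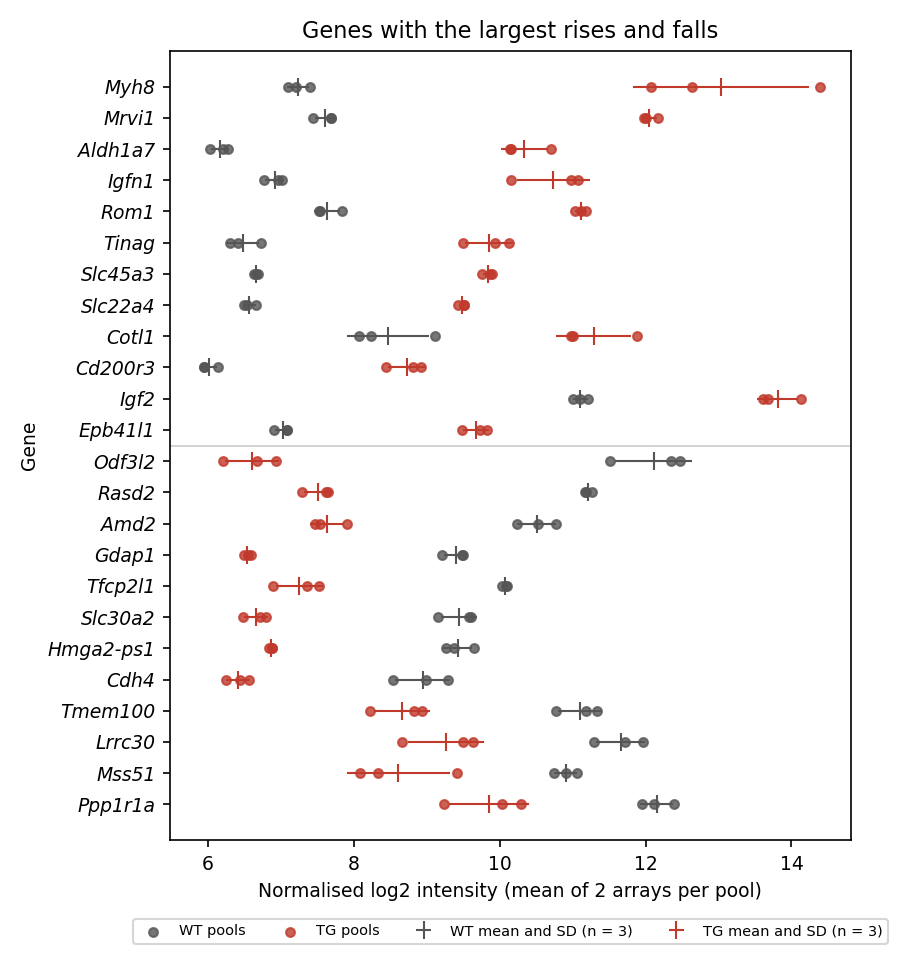
Normalised log2 intensity (x axis, mean of 2 arrays per pool) of the genes with the 12 largest rises and 12 largest falls in TG, with each pool as a point and the mean and SD of 3 pools as a tick and bar. The TG pools of Myh8 average 13.0 against 7.24 in WT, and those of Odf3l2 6.61 against 12.1.

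In all, 4060 of 15708 probes passed an adjusted p of 0.05 by limma, 1771 higher and 2289 lower in TG. Counted as genes with 1 probe each, 2558 of 9131 passed, 1106 higher and 1452 lower. The counts per list below are to be read against this share. Calls in either direction did not exceed it in several lists, among them slow-fibre, fast-fibre, fatty acid, oxidative phosphorylation, PPAR and PGC-1, and mitochondrial ribosome. A change of at least 1.5-fold was seen for 1140 probes (621 higher, 519 lower) and of at least 2-fold for 363 (223 higher, 140 lower). The 3 TG and 3 WT pools did not overlap at 7105 probes, or 45.2%, where chance gives 10%. Higher probes made up 43.6% of the calls, 33.5% of 4337 with 75th percentile scaling and 51.1% of 4076 with cyclic loess. Which direction had more calls thus depended on the scaling. Chip 1 alone gave 3491 calls and chip 2 alone 1457, and 4903 were called with the chip as a block and the pool as a random block. Leaving out a pool moved the count by over 1.5 times for WT1 (2588 calls), WT2 (2062) and WT3 (2583). Of 148 named genes, 18 lost a call on chip 1 alone and 46 on chip 2 alone. With WT1 taken from chip 1 only and TG3 left out, chosen after seeing the data, 4489 probes were called.

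Transcripts of carbohydrate and mitochondrial energy metabolism were in part higher in TG muscle. The gene lists here were fixed before the data were examined. In the TCA cycle list 8 of 20 genes rose, 0 fell and 12 did not pass (10 passed when adjusted over the list alone). Among them were Dlst (log2 0.78 ± 0.09, SE) and Dlat (0.74 ± 0.09), subunits of the oxoglutarate and pyruvate dehydrogenase complexes, and Sdhd (0.55 ± 0.07), a subunit of succinate dehydrogenase. Dlst had 4 kept probes, of which 2 were called, with differences from -0.11 to 0.78. Idh2 had a negative difference (-0.24) and passed only when adjusted over the list alone. Of 66 oxidative phosphorylation genes, 17 rose, 1 fell and 48 did not pass (18 adjusted over the list alone). Among these were Ndufb7 of complex I at 0.50 ± 0.07, Cyc1 of complex III at 0.50 ± 0.08, and Cox8b, the muscle isoform of a cytochrome oxidase subunit, at -0.38 ± 0.07. Of 17 glycolysis genes 6 rose, including Pgk1 (0.91 ± 0.07) and the muscle pyruvate kinase gene Pkm (0.48 ± 0.07), 1 fell, the glucose transporter gene Slc2a1 (-0.69 ± 0.12), and 10 did not pass (7 adjusted over the list alone). Sdhd did not pass on chip 2 alone (0.45), Ndufb7 in the authors' deposited table (0.43), and Cox8b there (-0.27) or with 75th percentile scaling (-0.29).

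By camera the TCA cycle list (median 0.19, adjusted p = 0.00119), the oxidative phosphorylation list (0.12, adjusted p = 0.000478) and the glycolysis list (0.16, adjusted p = 0.0212) were shifted up relative to other genes, and each had an adjusted p of 0.584 with an estimated correlation. On chip 1 and chip 2 the medians were 0.21 and 0.23 for the TCA cycle, 0.10 and 0.14 for oxidative phosphorylation, and 0.13 and 0.16 for glycolysis. The glycolysis call was lost on chip 1 alone (adjusted p = 0.058 by camera) and with WT1 from chip 1 only (0.0585), over a range of 0.000763 to 0.584 among its alternatives. In the authors' deposited table the medians were larger, at 0.35 for glycolysis and 0.21 for oxidative phosphorylation, as with 75th percentile scaling (0.29 and 0.19).

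Genes of glycogen metabolism moved in both directions, with 4 of 16 higher, 4 lower and 8 not passing (8 adjusted over the list alone). Stbd1, a glycogen-binding protein (log2 2.54 ± 0.17, SE), and Fbp2, the muscle fructose bisphosphatase (2.14 ± 0.11), rose, and Gaa, the lysosomal acid glucosidase (-0.81 ± 0.08), and Ppp1r1a fell. The list median was 0.04 (0.09 on chip 1 and 0.01 on chip 2), with an adjusted p of 0.791 by camera. In fatty acid uptake and oxidation 4 of 28 genes rose, 3 fell and 21 did not pass (9 adjusted over the list alone). Acads, the short-chain acyl-CoA dehydrogenase (0.96 ± 0.07), Acsl6, an acyl-CoA synthetase (0.98 ± 0.09), and Crat, carnitine acetyltransferase (0.55 ± 0.10), were higher, and Fabp3, the heart-type fatty acid binding protein (-0.34 ± 0.07), was lower, though not past the threshold without WT2 (-0.33). Its median was -0.09 (-0.10 on chip 1 and -0.02 on chip 2), its mean -0.0064, its camera direction down (adjusted p = 0.867) and its fry direction up. Among 19 PPAR and PGC-1 regulators, Ppargc1b, a coactivator of mitochondrial gene expression (0.71 ± 0.14), and Pparg (0.37 ± 0.10) rose, Esrrb (-0.63 ± 0.16) and Med1 (-0.29 ± 0.07) fell. The remaining 15 did not pass (4 adjusted over the list alone). With single pools left out, Esrrb did not pass without WT2 or WT3 (-0.59 in either), Med1 without WT1, WT2, TG1 or TG2 (-0.30 to -0.25) and Pparg in any case but without TG3 (0.28 to 0.38). On chip 2 alone Fabp3 (-0.27), Ppargc1b (0.74), Pparg (0.33), Esrrb (-0.51) and Med1 (-0.20) did not pass. In the authors' deposited table Crat (0.49), Fabp3 (-0.25) and Pparg (0.52) did not. The median of this list was -0.06 (-0.03 on chip 1, -0.06 on chip 2) and its mean 0.02, with an adjusted p of 0.867 by camera (direction up, and down by fry).

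Contractile genes passed no more often than all tested genes (2558 of 9131). Several fast-fibre genes, such as Actn3 (15.6 in WT) and Myh4 (15.2), lay near the top of the intensity scale. So did some energy metabolism genes, such as Eno3 of glycolysis (15.6). Differences there may be compressed, which was not tested, so genes that did not pass are not shown to be unchanged. The called slow-fibre genes rose, and the called fast-fibre genes changed in both directions. Of 11 slow-fibre genes 3 rose, 0 fell and 8 did not pass (7 adjusted over the list alone). Of these 7, Myl3 had a negative difference (log2 -0.52). The rises were those of Tnni1, slow troponin I (log2 0.93 ± 0.15, SE), the calcium store protein Casq2 (0.60 ± 0.13) and Tpm3, slow tropomyosin (0.45 ± 0.12). Myh7, slow myosin heavy chain, measured 0.27 ± 0.08 and did not pass. It passed in 8 settings, such as without background correction (0.75), in the authors' deposited table (0.77), with neqc (0.51) and without TG3 (0.32). Casq2 did not pass without WT1 or WT3 (0.58 in either), nor Tpm3 without WT2, WT3, TG1 or TG2 (0.36 to 0.45), nor either on chip 2 alone (0.64 and 0.36). The slow-fibre median was 0.27 (0.30 on chip 1 and 0.24 on chip 2), with an adjusted p of 0.0912 by camera. This p was 0.0241 without WT1, 0.0463 on chip 2 alone and 0.0244 without the filter on dim probes, in a range of 0.0241 to 0.745. Of 16 fast-fibre genes 2 rose, 2 fell and 12 did not pass (4 adjusted over the list alone). Mylk2, the myosin light chain kinase of skeletal muscle, fell (-2.06 ± 0.13), as did the fast myosin Myh4 (-0.22 ± 0.06), whereas Myh1, another fast myosin (0.36 ± 0.07), and the calcium buffer Pvalb (0.23 ± 0.07) rose. With single pools left out, Myh4 passed only without TG3 and Pvalb never, with log2 differences from -0.23 to -0.21 and from 0.20 to 0.27. Neither passed on chip 1 or chip 2 alone. Myh1 did not pass on chip 2 alone (0.18), in the authors' deposited table (0.34) or with the chip as a block and the pool as a random block (0.36). Myh4 was -0.12 with 75th percentile scaling and -0.11 in the authors' table, passing in neither, and Pvalb was 0.42 and 0.44 there, passing with the scaling. The fast-fibre median of -0.04 (-0.01 on chip 1, -0.07 on chip 2) had an adjusted p of 0.791 by camera and of 0.0164 by fry, in a range of 0.0164 to 0.96. It turned to 0.15 with 75th percentile scaling, 0.07 with cyclic loess and 0.17 in the authors' deposited table.

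In the growth and IGF-mTOR list 5 of 23 genes rose, 3 fell and 15 did not pass (8 adjusted over the list alone). Beside Igf2 the rises included Grb14, an adaptor that inhibits the insulin receptor (log2 1.74 ± 0.08, SE), and Igf1 (0.82 ± 0.12), while Acvr1b, an activin type I receptor, fell (-1.33 ± 0.11, and -2.37 without background correction). Igf1 did not pass on chip 2 alone (0.62, adjusted p = 0.0904 by limma, in a range of 0.00134 to 0.0904). The list had a median of 0.00058 (0.03 on chip 1, 0.01 on chip 2) and a mean of 0.22, with an adjusted p of 0.243 by camera, and the sign of its median turned in several settings, such as without TG2 (-0.0045). By fry the list was called (adjusted p = 0.00881, in a range of 0.00881 to 0.584).

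Genes of atrophy and proteolysis were more often lower than higher in TG, with 10 of 21 lower, 2 higher and 9 not passing (15 adjusted over the list alone). Sqstm1, an autophagy receptor (log2 -0.59 ± 0.07, SE), and Fbxo21, an F-box protein (-0.58 ± 0.08), fell, whereas Map1lc3a, a protein of autophagosome membranes (1.43 ± 0.14), and Gadd45a, a stress-induced gene that rises after denervation (1.38 ± 0.13), rose. Chosen after their values were seen, the muscle ubiquitin ligase genes Trim63 (-1.77 ± 0.30) and Fbxo32 (-1.46 ± 0.23) and Foxo1, a transcription factor that activates both (-1.05 ± 0.18), also fell. The list was shifted down (median -0.45, -0.33 on chip 1 and -0.46 on chip 2) with an adjusted p of 0.044 by camera, and an adjusted p of 0.793 with an estimated correlation. The pool means overlapped, at 10.8 for both WT3 and TG2. The camera call was lost without WT1 (adjusted p = 0.138) or TG1 (0.0844) and with WT1 from chip 1 only (0.0746), in a range of 0.00227 to 0.793 among its alternatives. It was also lost without background correction (0.0642), with 75th percentile scaling (0.0738), in the authors' deposited table (0.0909), with neqc (0.0536) and by fry (adjusted p = 0.111). The median was -0.21 without the filter on dim probes. Of 15 glucocorticoid response genes, 6 of them shared with another list, 5 fell, 0 rose and 10 did not pass (5 adjusted over the list alone). These included the clock gene Per1 (-0.78 ± 0.14) and Glul, glutamine synthetase (-0.90 ± 0.18). Per1 did not pass on chip 1 alone (-0.54) nor Glul on chip 2 alone (-0.81). The glucocorticoid list had a median of -0.26 (-0.18 on chip 1, -0.37 on chip 2) and an adjusted p of 0.0475 by camera, and an adjusted p of 0.793 with an estimated correlation. That call was lost on chip 1 alone (adjusted p = 0.402 by camera), with the chip as a block (0.0822), without WT1 (0.181), WT2 (0.0981), TG1 (0.143) or TG3 (0.101, with a median of -0.13) and with WT1 from chip 1 only (0.119, and 0.194 with TG3 also left out), in a range of 0.0027 to 0.793. It was also lost without background correction (0.0642), with 75th percentile scaling (0.113), in the authors' deposited table (0.135), with neqc (0.0536), with averaged probes (0.0511) and by fry (adjusted p = 0.192), and held in 8 of 24 alternatives.

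Of 17 genes that mark denervated or regenerating muscle 9 rose, 1 fell and 7 did not pass (13 adjusted over the list alone). Beside Myh8 and Gadd45a they included Actc1, cardiac actin (log2 1.21 ± 0.12, SE), and Chrnb1, the beta subunit of the muscle acetylcholine receptor (0.96 ± 0.13). Chosen after their values were seen, Myl4, the embryonic and atrial myosin light chain (2.01 ± 0.37), and Chrng, the fetal subunit of that receptor (1.80 ± 0.56, adjusted p = 0.0487 by limma), also rose, while Musk, the receptor kinase of the neuromuscular junction (-0.77 ± 0.14), fell. Chrng did not pass without WT1 (1.93), WT2 (1.70) or WT3 (1.76), and was 1.02 without TG3. On chip 2 alone neither Chrng (1.57) nor Musk (-0.52) passed, and without background correction they were 3.35 and -1.46. The list was shifted up (median 0.63, 0.76 on chip 1 and 0.71 on chip 2) with an adjusted p of 0.00209 by camera, and an adjusted p of 0.584 with an estimated correlation. Its mean was 10.9 in pool TG3, which also had the highest macrophage list mean, against 10.1 in both other TG pools. The median was 1.11 without background correction.

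Of 14 interferon response genes 10 rose, 0 fell and 4 did not pass (10 adjusted over the list alone). Rsad2, an antiviral enzyme (log2 0.75 ± 0.10, SE), Irf9, a transcription factor of interferon signalling (0.59 ± 0.08, and 1.01 without background correction), and Psmb8, a subunit of the immunoproteasome (0.47 ± 0.09, not past the threshold on chip 1 alone at 0.35), were among them. The list median of 0.45 (0.39 on chip 1, 0.49 on chip 2) had an adjusted p of 0.000151 by camera, and an adjusted p of 0.584 with an estimated correlation. In the macrophage and leukocyte list 3 of 14 genes rose, 0 fell and 11 did not pass (3 adjusted over the list alone). The 3 were the antigen presentation genes H2-Ab1 (1.66 ± 0.36), Cd74 (1.40 ± 0.35) and H2-Aa (1.31 ± 0.38). With single pools left out, H2-Ab1 did not pass without WT2, Cd74 without WT1, WT2 or WT3, and H2-Aa without WT1, WT2, WT3 or TG2. Their log2 differences ranged from 1.19 to 1.95, 0.94 to 1.69 and 0.79 to 1.62, each lowest without TG3, and none passed on chip 2 alone. Lyz1, a lysozyme with a close copy in Lyz2, measured 1.06 ± 0.45 and did not pass. It was 0.55 without TG3, and passed on chip 1 alone (1.55) and with WT1 from chip 1 only (1.46). The macrophage list was shifted up (median 1.04, 1.52 on chip 1 and 0.59 on chip 2) with an adjusted p of 0.00633 by camera, and an adjusted p of 0.793 with an estimated correlation. By fry the call was lost (adjusted p = 0.26). Its median was 0.41 without TG3 and 1.42 without TG1. Its mean was 10.6 in pool TG3 against 8.79 in TG1 and 8.95 in TG2. Among the WT arrays it was 9.87 on the chip 2 array of WT1 and 7.99 on its chip 1 array.

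**Figure D3:**
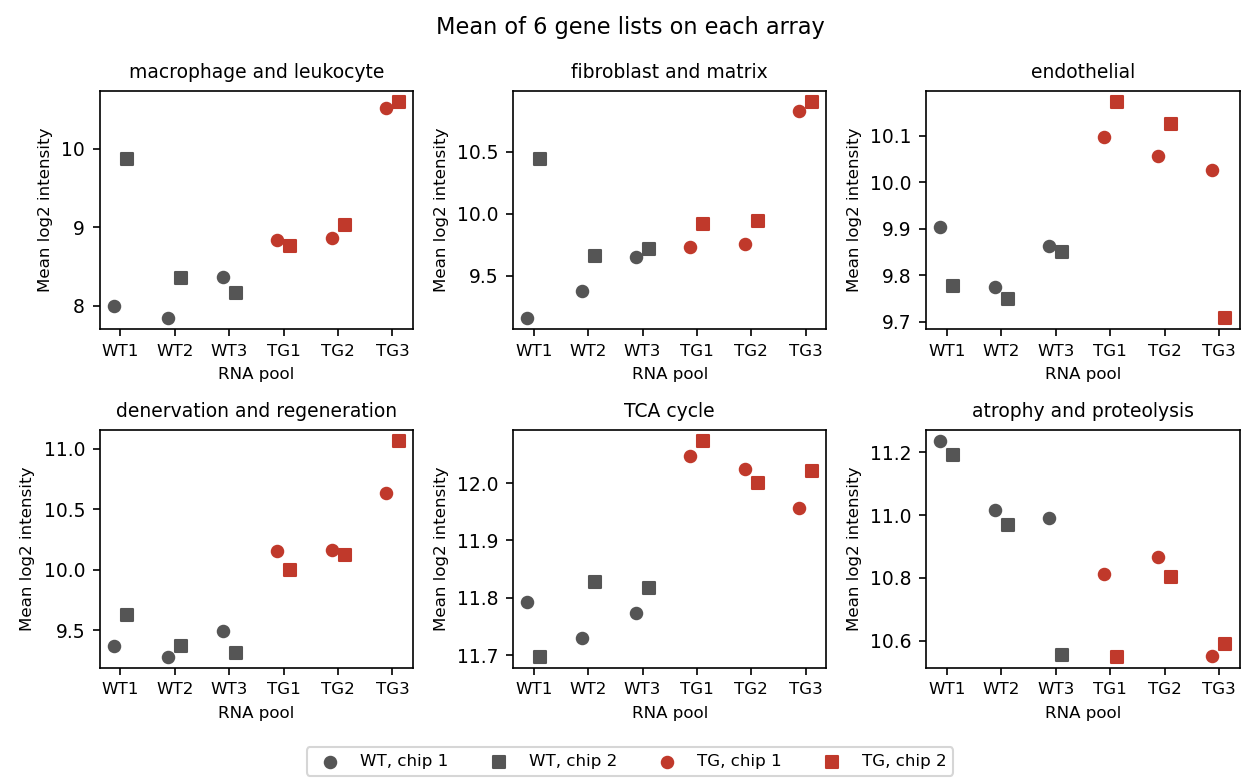
Mean normalised log2 intensity (y axis, scaled separately in each panel) of 6 gene lists on each of the 12 arrays, by RNA pool (x axis), with chip 1 as circles and chip 2 as squares. The macrophage and leukocyte mean is 9.87 on the chip 2 array of WT1 and 10.5 and 10.6 on the TG3 arrays, and the TCA cycle mean is higher on the 6 TG arrays than on the 6 WT arrays.

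Among markers of other cell types, 2 of 17 fibroblast and matrix genes rose, Mgp, a matrix calcification inhibitor (log2 0.94 ± 0.19, SE), and the collagen VI gene Col6a2 (1.02 ± 0.27), 0 fell and 15 did not pass (2 adjusted over the list alone). Col6a2 did not pass without WT1, WT2 or WT3 (log2 0.97 to 1.10), and was 0.67 without TG3. On chip 2 alone neither Mgp (0.81) nor Col6a2 (0.90) passed. The fibroblast list was shifted up (median 0.37, 0.55 on chip 1 and 0.23 on chip 2) with an adjusted p of 0.0212 by camera, and an adjusted p of 0.82 with an estimated correlation. That call was lost on chip 2 alone (adjusted p = 0.0932 by camera) and without TG3 (median 0.13, adjusted p = 0.185), in a range of 0.00156 to 0.82, and by fry (adjusted p = 0.337). Without TG2 the median was 0.58, and 0.67 with WT1 from chip 1 only. The list mean was highest on the arrays with the highest macrophage means (10.4 on chip 2 of WT1, 10.8 and 10.9 on TG3). Of 12 endothelial genes 3 rose, Emcn (0.30 ± 0.07), Eng (0.31 ± 0.08) and Pecam1 (0.35 ± 0.11), 0 fell and 9 did not pass (3 adjusted over the list alone). Each of the 3 lost its call without WT1, WT2, WT3 or TG1, Emcn also with WT1 from chip 1 only (0.24), and Pecam1 with any pool left out. With single pools left out they ranged from 0.26 to 0.33, 0.27 to 0.37 and 0.24 to 0.41. Emcn did not pass on chip 1 alone (0.14), Eng (0.24) and Pecam1 (0.23) on chip 2 alone, nor any of them with 75th percentile scaling (0.19, 0.23 and 0.25) or in the authors' deposited table. The endothelial list (median 0.24, 0.23 on either chip) had an adjusted p of 0.0212 by camera, and an adjusted p of 0.743 with an estimated correlation. That call was lost on chip 2 alone (adjusted p = 0.077 by camera), without TG1 (0.0951) or TG2 (0.0584) and with WT1 from chip 1 only (0.0651), in a range of 0.000896 to 0.743. It was also lost with 75th percentile scaling (median 0.15, adjusted p = 0.0738), in the authors' deposited table (median 0.18, adjusted p = 0.15) and by fry (adjusted p = 0.115). Of 7 satellite cell genes 3 rose, among them Itga7, a laminin-binding integrin (0.85 ± 0.15), and Vcam1 (0.72 ± 0.16, not past the threshold without WT1, WT2 or WT3, at 0.68 to 0.74, or on chip 2 alone, at 0.66, and 1.25 without background correction), 0 fell and 4 did not pass (4 adjusted over the list alone). The satellite cell median was 0.16 (0.20 on chip 1, 0.18 on chip 2), with an adjusted p of 0.123 by camera. The list was called without the filter on dim probes (adjusted p = 0.0327) and by fry (adjusted p = 0.0164), in a range of 0.0164 to 0.584. Of the 4 genes that passed over the list alone, Cdh15 had a negative difference (-0.29). Of 9 smooth muscle and pericyte genes 1 rose, Smtn (0.37 ± 0.11, past the threshold only without WT3 among the pools left out, at 0.27 to 0.47), 0 fell and 8 did not pass (0 adjusted over the list alone). Smtn passed on neither chip alone. The smooth muscle median was 0.15 (0.18 on chip 1, 0.13 on chip 2, adjusted p = 0.146 by camera). Of 6 nerve and Schwann cell genes 1 fell, Ncmap (-0.32 ± 0.09, lost without WT1, WT2, WT3 or TG1, at -0.37 to -0.27), 0 rose and 5 did not pass (1 adjusted over the list alone). Ncmap passed on neither chip alone, and was -1.04 without background correction. The nerve median was -0.04 (-0.11 on chip 1, 0.0024 on chip 2, adjusted p = 0.867 by camera). None of the 4 adipocyte genes passed (0 adjusted over the list alone), and their median was 0.14 (-0.02 on chip 1, 0.28 on chip 2, adjusted p = 0.867 by camera).

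In total camera called 10 of the 30 lists tested, 0 with an estimated correlation, and fry, which asks only whether the genes of a list move one way on balance, called 11. Other splits of the 6 pools into groups of 3 gave between 4 and 12 lists by camera, and 0 probes by limma. These splits mixed the genotypes within groups, so their counts do not measure chance. Since 4 of 10 splits, the real one included, gave at least as many lists, the number of lists called does not set the genotype split apart.

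The chip was the one batch the labels gave, and both genotypes lay on both chips. No probe differed between chips by limma at an adjusted p of 0.05 (0 of 15708, smallest adjusted p = 0.0583, with 1308 at an unadjusted p below 0.05). The genotype difference depended on the chip at 0 probes by limma (smallest adjusted p = 0.603, with 893 at an unadjusted p below 0.05). The largest differences between the 2 arrays of WT1, chosen after their values were seen, were those of Timp1, an inhibitor of matrix proteases (log2 4.49, chip 2 minus chip 1), Mpeg1, a macrophage pore-forming protein (3.59), and Lgals3, a galectin of activated macrophages (3.31).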

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

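The tests of a transgenic array in the place of the chip 2 array of WT1 and of different RNA on the arrays of a pool were chosen only after the result was seen. The bound of both covariate tests on the atrophy list was also tightened after the first output, because a median alone ignores the spread over 6 pools.

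Among 118 groups of 6 arrays (3 pools on 2 chips), Dixon's test marked 14 single arrays as far from the rest. Its nominal rate of about 1 in 20 holds for 6 independent values and separate groups. Here arrays shared pools and the groups shared arrays, so the 14 cannot be weighed against that rate. Of the 14, 5 were the chip 2 array of WT1. On that array the list means of the cytosolic ribosome (13.3), macrophage and leukocyte (9.87) and cell cycle (7.88) genes and the level of Cotl1 (10.3) were the highest among WT arrays, and Mrvi1 (7.12) was the lowest. On the chip 1 array of WT1 the maximum signal (40194.2) was the lowest and the lipid synthesis and storage mean (8.89) the highest among WT arrays. On the chip 2 array of TG3 the satellite cell mean (8.78) and Aldh1a7 (11.0) were the highest among TG arrays, and the endothelial mean (9.71), the smooth muscle and pericyte mean (8.63) and Cd200r3 (8.19) the lowest. In WT3 the antioxidant mean was the lowest among WT arrays on chip 2 (10.4) and the interferon mean the highest on chip 1 (8.32).

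The arrays of a pool were often no closer to each other than to arrays of other pools, with the same pool nearest for 2 of 12 arrays. The brighter probes also gave 2 of 12, which met the bound set in advance against noise of dim probes. The chips were not centred in that count, so a whole-chip shift could have kept it low. The count therefore cannot decide about noise. The labelled pairing across the chips ranked 3 of 36 by mean correlation of residuals (0.234, against 0.28 for the best other pairing, whose lowest pair was at 0.0759), so a whole-chip shift and crossed pool numbers stay open. The labelled pairs correlated at 0.38, 0.32 and 0.57 in TG1, TG2 and TG3, but at 0.06, 0.11 and -0.03 in WT1, WT2 and WT3. The TG3 arrays thus matched each other and not the other TG pools (-0.47 to -0.42). TG1 and TG2 matched across pools as well (0.33 and 0.32), and the WT arrays did not sort by pool. Different RNA on the arrays of a pool, such as RNA of single mice, would go against the labels and stays open. The within-pool correlation of 0.138 restates the pattern, so it gives no separate evidence for this explanation. With 12 mice and 12 arrays the values do not decide it. No biological explanation was tested, and 5513 probes were called when all 12 arrays were taken as independent.

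Macrophage genes were high on the chip 2 array of WT1 and on both TG3 arrays, with 14 of 14 list members highest there among the arrays of their genotype (0 of them in another list, 13 detected on all WT arrays) and list means 1.72 and 1.69 log2 units above the rest of the arrays of that genotype. A transgenic array in the place of WT1 was argued against, because it lay nearer the WT mean at 94.1% of 339 genotype probes, and admixed TG3 RNA was too, because 209 probes higher in TG needed a share of 0.00671 where the macrophage list needed 0.592. A lower share of muscle RNA that raises all other cell types alike was argued against by the endothelial and smooth muscle lists. Their largest excess was -0.0508, while the fibroblast list was higher by 0.93 and 1.03. More RNA of macrophages and fibroblasts would itself lower the share of muscle RNA, and no muscle list was compared. The test therefore cannot exclude a lower share of that kind. More leukocytes in the tissue may be a candidate explanation and was not tested. It leaves open why 1 array of WT1 carried the excess and the other did not, and different RNA on its arrays (above) stays open too.

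The atrophy and proteolysis list was lower in TG, and the transgene stays among the open explanations, untested. Over the 19 genes not shared with the glucocorticoid or clock lists the median was -0.45. With the glucocorticoid list mean as a covariate the median was -0.30 and the list mean -0.24 ± 0.11 (SE), against -0.38 without it. With the clock list mean, standing for the time of collection, the median was -0.54, which met the bound set in advance against that explanation, but the list mean was -0.41 ± 0.25 (SE), too wide a spread over 6 pools for that bound to decide. Neither state of the animals can therefore be told apart from genotype here, and an exact permutation of the list means gave p = 0.2.

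With 3 against 3 pools there are 10 splits, too few for a share under 0.05. Each of the other splits mixed WT and TG pools, so a genotype difference widened the spread within groups. Counts from these splits therefore do not measure chance. The real split gave 4060 probes and the highest other split 0, so 1 of the 10 splits, the real one, gave as many. For lists called by camera the real split gave 10 and the highest other 12, with 4 of 10 splits at 10 or more. The number of lists called by camera therefore does not set the genotype split apart from the others. For the dependence of the genotype difference on the chip, the real split and the highest other gave 0, so all 10 splits were as large.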

How the results depend on the processing

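The neqc setting and the settings with WT1 from chip 1 only, with or without TG3, were chosen only after the result was seen. Signal over background limits Nr4a1 and the genes undetected in 1 genotype, and 3 pools limit the rest. The 24 genes with the largest changes kept their call and direction in all 497 results under alternatives. Among the other 124 named genes, 97 of them called, 2235 of 2599 results stayed on their side of the threshold and kept direction, 286 lost and 72 gained a call, 6 changed sign and 0 of those were called. Of 720 list results 631 were kept, 48 lost a call, 11 gained one, 30 changed sign and 0 of those were called. All 4060 called probes kept their direction in each setting that tested them, except 4057 of 4060 on chip 2 alone. The cause of a change was not tested where none is named.

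Chip 2 alone called 1457 probes (721 higher, 736 lower), at least 1.5-fold left 1140 (621, 519), and 1 probe per gene left 2652 (1152, 1500), the last with fewer probes tested. Leaving out a pool, which leaves fewer samples, gave 2062 (without WT2) to 4220 (without TG3) probes, 977 to 2035 of them higher and 1085 to 2185 lower. The other settings gave between 3022 (the authors' deposited table) and 5557 (adjusted p below 0.1), with 5513 for 12 arrays as independent. Without the filter on dim probes 5 probes differed between chips.

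Nr4a1 turned from -0.02 to 0.55 in the authors' deposited table, 0.010 with neqc, 0.018 on chip 1 alone and 0.022 with WT1 from chip 1 only, and ranged from -0.052 to 0.0050 with a pool left out. Its probe was detected on 0 arrays.

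Camera with an estimated correlation called 0 lists, with unchanged medians for glycolysis (0.16), TCA cycle (0.19), oxidative phosphorylation (0.12) and atrophy (-0.45). WT1 from chip 1 only gave 6 lists. Calls for glycolysis were lost on chip 1 alone (0.13), with WT1 from chip 1 only (0.14) and with TG3 also left out (0.12). For atrophy they were lost with no background correction (-0.45), 75th percentile scaling (-0.49), the authors' table (-0.46), neqc (-0.45), WT1 from chip 1 only (-0.40), that without TG3 (-0.26) and fry (-0.45), and the median ranged from -0.57 to -0.30 with a pool left out. The slow-fibre list was called without the filter (0.27), on chip 2 alone (0.24) and without WT1, with a median of 0.20 to 0.32 when a pool was left out. Fry called the fast-fibre (-0.038), growth (0.00058), lipid synthesis (0.11), satellite cell (0.16), antioxidant (-0.17) and clock (-0.25) lists, and lost the atrophy, glucocorticoid (-0.26), endothelial (0.24), fibroblast (0.37) and macrophage (1.04) calls. The glucocorticoid call held in 8 of 24 alternatives and the endothelial in 16. The satellite cell list was also called without the filter (0.13), and the clock list on chip 2 alone (-0.30).

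Medians that changed sign belonged to lists that were not called. The fast-fibre list gave 0.15 with 75th percentile scaling, 0.073 with cyclic loess and 0.17 in the authors' table. The growth list gave -0.086 with 75th percentile scaling, -0.088 in the authors' table, -0.011 without the filter, -0.017 with the strict detection filter, -0.0062 with WT1 from chip 1 only, and -0.0045 to 0.13 with a pool left out. Glycogen metabolism gave -0.063 in the authors' table and -0.0040 with WT1 from chip 1 only. With 75th percentile scaling and in the authors' table the mitochondrial ribosome gave -0.022 and -0.0063, the cytosolic ribosome 0.0091 and 0.0079, and AMPK -0.020 and -0.0041. Adipocyte genes gave -0.11 without the filter and -0.019 on chip 1. Heat shock genes gave 0.0077 on chip 1 and -0.13 to 0.0066 with a pool left out. Nerve genes gave 0.0024 on chip 2, 0.026 with WT1 from chip 1 only and no TG3, and -0.11 to 0.065 with a pool left out. Cell cycle genes gave -0.085 on chip 2 and -0.063 to 0.17, and immediate-early genes -0.0040 to 0.19, with a pool left out. Of single genes, not called, Car3 gave 0.00016 with WT1 from chip 1 only and no TG3 and -0.34 to 0.063 with a pool left out, Alas2 -0.16 and Kdm5d 0.056 on chip 2, and Pmp22 -0.042 on chip 1.

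Same-numbered pools correlated at -0.42, 0.34 and -0.12 in their deviations from the group means, and not every pool correlated best with its own number. The deviations of 3 pools from their mean depend on each other, and WT1 and TG3, which had high macrophage means, correlated at 0.43. These correlations therefore cannot decide whether the pool numbers in the labels pair the pools. With the pool number as a replicate block 3101 probes and 10 lists were called.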

Other observations

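The test of neighbouring genes was chosen only after the result was seen; the gene lists were fixed before the data were examined.

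In the amino acid metabolism list 3 of 25 genes rose, 4 fell and 18 did not pass (13 adjusted over the list alone). Odc1, the rate-limiting enzyme of polyamine synthesis, fell (log2 -1.50 ± 0.09, SE, n = 3 pools per genotype), Smox, spermine oxidase, rose (1.05 ± 0.17), and Glul (-0.90 ± 0.18) and Gpt2, a mitochondrial alanine aminotransferase (-0.61 ± 0.15), fell, the last not past the threshold without WT1 or WT2 (-0.59 in either). On chip 2 alone Glul (-0.81) and Gpt2 (-0.63) did not pass. The amino acid median was -0.21 (-0.20 on chip 1, -0.07 on chip 2), with an adjusted p of 0.642 by camera. In lipid synthesis and storage 7 of 28 genes rose, 2 fell and 19 did not pass (11 adjusted over the list alone). The lipid droplet gene Cidea measured 1.20 ± 0.09, the elongase Elovl5 0.46 ± 0.08 and Plin4, a lipid droplet coat protein, -0.85 ± 0.15 (list median 0.11, 0.11 on either chip, camera adjusted p = 0.243, 0.0312 by fry, in a range of 0.0312 to 0.681). The lipid list median was 0.026 without TG3 and 0.16 without WT1. Elovl5 did not pass in the authors' deposited table (0.39). Of 22 antioxidant genes 2 rose, among them Txn2 (0.49 ± 0.07), 5 fell, among them Gstm2 (-1.16 ± 0.12) and Srxn1 (-0.85 ± 0.17), and 15 did not pass (8 adjusted over the list alone). Txn2 did not pass in the authors' table (0.41) nor Srxn1 on chip 2 alone (-0.67). The antioxidant median was -0.17 (-0.25 on chip 1, -0.15 on chip 2, camera adjusted p = 0.506, 0.0455 by fry, in a range of 0.0455 to 0.763). With single pools left out it ranged from -0.20 (without TG2) to -0.09 (without WT1). Of 12 clock genes 4 fell, Cry2 (-0.70 ± 0.10), Per1 (-0.78 ± 0.14), Rora (-0.36 ± 0.09) and Nr1d1 (-0.53 ± 0.15), 0 rose and 8 did not pass (4 adjusted over the list alone). Rora was lost without WT1, WT2 or TG2 (-0.39 to -0.28) and Nr1d1 without WT1 or WT3 (-0.54 and -0.42). On chip 1 alone Per1 (-0.54) and Rora (-0.32) did not pass, and on chip 2 alone Cry2 (-0.69) and Nr1d1 (-0.41). The clock list had a median of -0.25 (-0.09 on chip 1, -0.30 on chip 2), a camera adjusted p of 0.165 and, on chip 2 alone, of 0.0393, and by fry of 0.0455, in a range of 0.0393 to 0.599. Its median was -0.12 without TG3 and -0.29 without WT3.

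Of 55 mitochondrial ribosome genes 8 rose, among them Mrpl4 (0.35 ± 0.07, SE) and Mrpl12 (0.37 ± 0.08), 6 fell and 41 did not pass (17 adjusted over the list alone), and the list median was 0.07 (0.01 on chip 1, 0.06 on chip 2, camera adjusted p = 0.243). Mrpl4 did not pass on chip 1 alone (0.13) nor Mrpl12 on chip 2 alone (0.35), and neither passed in the authors' deposited table (0.27 and 0.33). Of 37 cytosolic ribosome genes 2 rose, 3 fell, among them Rpl22 (-0.51 ± 0.09, lost on chip 2 alone at -0.38), and 32 did not pass (5 adjusted over the list alone). The cytosolic ribosome median was -0.05 (-0.06 on either chip, camera adjusted p = 0.642). Both ribosome medians changed sign with 75th percentile scaling and in the authors' deposited table. Of 23 heat shock and unfolded protein genes 1 rose, Atf5 (0.54 ± 0.08, lost in the authors' table at 0.47), 4 fell, among them Hsph1 (-0.59 ± 0.08, lost on chip 1 alone at -0.32), and 18 did not pass (5 adjusted over the list alone). The heat shock median was -0.11 (0.0077 on chip 1, -0.13 on chip 2, camera adjusted p = 0.66). Of 12 AMPK and energy sensing genes 1 fell, Prkag3, the muscle-specific gamma subunit of AMPK (-0.97 ± 0.20, lost on chip 2 alone at -1.03), 0 rose and 11 did not pass (1 adjusted over the list alone). The AMPK list had a median of 0.07 (0.02 on chip 1, 0.01 on chip 2), a mean of -0.03 and a camera adjusted p of 0.867 (direction up). Of 15 immediate-early genes 2 fell, Maff (-0.35 ± 0.07, lost without WT2 at -0.34) and Ccn1 (-0.36 ± 0.11, lost without WT1, WT2, TG1 or TG2 at -0.36 to -0.26), 0 rose and 13 did not pass (1 adjusted over the list alone). Maff was -1.13 without background correction. It did not pass on chip 2 alone (-0.30) nor Ccn1 on either chip. Egr1 measured 0.99 ± 0.31 and did not pass, though it did on chip 2 alone (1.44) and without WT1 (1.33) or TG1 (1.19), against 0.53 on chip 1 alone. The immediate-early median was 0.08 (0.18 on chip 1, 0.09 on chip 2, camera adjusted p = 0.66). Of 10 cell cycle genes Cenpa rose (0.86 ± 0.21, lost without WT2 or WT3, at 0.71 and 0.86, and on chip 2 alone, at 0.76), Mcm7 fell (-0.30 ± 0.09, kept only without TG2 among the pools left out, at -0.36, and on neither chip alone, and -0.56 without background correction) and 8 did not pass (2 adjusted over the list alone). The cell cycle median was 0.06 (0.23 on chip 1, -0.08 on chip 2, camera adjusted p = 0.867). Hba-a1 and Alas2 of blood (0.25 ± 0.18 and 0.11 ± 0.12) and the Y-linked Eif2s3y and Kdm5d (-0.16 ± 0.07 and -0.10 ± 0.07) did not pass, though Eif2s3y did with 75th percentile scaling (-0.27).

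A hypothesis was tested that some of the 231 genes changed at least 2-fold are neighbours of the transgene's insertion or were carried along from another strain, which could place several of them side by side. Among 9124 placed genes the fullest window of 15 neighbouring genes held 4, and 1000 shuffles had a median of 4 and a 95th percentile of 5 (permutation p = 0.577). The test gave no sign of such a cluster, and a few genes near an insertion stay open.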
